A study of Mus musculus with 12 samples.

How the data were processed

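Quadriceps messenger RNA was sequenced from stranded polyA libraries, per the labels' protocols, in 12 libraries of 3 groups. Per the submitters' processing notes, reads were processed with STAR 2.6.1c, Subread and featureCounts 1.5.1 on mm10. The role of each tool, the strand setting, filters and the annotation release are not given in the sources used here. The authors deposited whole-number read counts per gene, which were used for every test, and RPKM values per gene with gene lengths, starts and ends, which served to check the counts and give positions. For each of the 12 libraries 1 deposited RPKM column of its own group was proportional to counts over length, with a coefficient of variation of at most 0.0864%. Among the counted genes, 27 symbols had been turned into dates and 3 genes had an identifier but no symbol. Those 3 held 0.0016% of reads, and identifiers were used for both kinds. Libraries of a group differed by a chi-square of 20.1 to 309 per gene, so none was taken for a copy of another.

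Groups came from the labels. Tests used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, total 15), libraries were scaled by TMM and 1 quasi-likelihood fit of group means held all 12 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values use the TMM-scaled library totals and are given as mean ± SD of 4 libraries. Standard errors of log2 fold changes are the fold change over the square root of the F statistic. Of the genes in 30 lists, 756 of 758 were found. Lists with at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry. Simulated data had 200 changed genes, each gene drawn independently of the others. There the test of old vehicle against young called 55% of 2-fold and 90% of 4-fold changes. Of its calls, 7.05% were false.

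The groups, tests, lists, rule for named genes and a set of other settings were fixed before the data were examined. Named genes were, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out predicted genes, Riken clones and pseudogenes. Up to 4 called members of each list by adjusted p, 14 fixed genes, and, where fewer than 10 genes were called, the 10 with the smallest p were added. Of the genes so named, 3 are not reported here. These settings were DESeq2 1.42.0, limma-voom, other scaling factors and filters, 2-group fits, a replicate block, robust shrinkage, a threshold of 0.1 and leaving out each library. A length slope as a covariate, surrogate variables (sva 3.50.0), library weights and a fit without 2 young libraries were chosen after seeing the data. For values with no test, a change was judged against the 95% Wilson interval of a percent or 1 SD of the leave-one-out values of a correlation. That rule replaced a wider one after its results had been seen. Opposite signs were also counted in 20 simulations of each kind and over all assignments of the old libraries. Intervals cover counting error only.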

Results

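Messenger RNA of mouse quadriceps, the large thigh muscle, was sequenced in 12 libraries from C57BL/6 mice in 3 groups of 4. Young mice were 6 months old. Both old groups were 24 months old and were gavaged from month 20 on 3 days in every 2 weeks, either with the vehicle alone (old vehicle) or with dasatinib at 5 mg/kg plus quercetin at 50 mg/kg (D+Q). Dasatinib is a tyrosine kinase inhibitor and quercetin a plant flavonoid, and the pair is used as a senolytic, a treatment meant to remove senescent cells. The labels state no gavage for the young mice, so age and gavage differ together between young and old vehicle. Library totals ran from 26715140 to 49792488 reads, with means of 37400000 ± 9010000 in young, 44500000 ± 4820000 in old vehicle and 44200000 ± 1220000 in D+Q (SD, n = 4). At these depths 3 reads correspond to between 0.0561 and 0.106 CPM. The labels do not say that each library is a separate mouse, and p-values measure the spread between these libraries. Of the 43346 listed genes, 16146 had enough reads to be tested. All 37 genes on the mitochondrial chromosome were listed at 0 reads in every library, so the list of mitochondrially encoded genes was not tested.

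The first comparison asked what differed between old vehicle and young muscle. Genes of the denervation and neuromuscular junction list, some of which muscle fibres raise when nerve contact is lost, were higher in old vehicle. All 25 tested members had a positive fold change and 12 rose past the threshold, 15 when adjusted over the list alone. Gadd45a, a stress and growth arrest gene also induced by denervation, went from 18.9 ± 1.43 CPM in young to 79.7 ± 16.5 CPM in old vehicle (SD, n = 4), 4.23-fold higher. Runx1, a transcription factor of denervated muscle, was 7.1-fold higher, Ankrd1, a stretch-responsive sarcomere protein, 9.85-fold higher, and Chrnb1, the beta subunit of the muscle acetylcholine receptor, 2.45-fold higher. Of 40 genes of collagens and other extracellular matrix proteins, 6 fell, among them the collagens Col1a2 and Col3a1, each 2.24-fold lower in old vehicle, and the matrix proteins Postn and Sparc. The list had adjusted p = 4.36e-08 in the set test camera and adjusted p = 0.425 with an estimated correlation.

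In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 300 genes passed, 195 higher and 105 lower, and 168 of them differed by over 2-fold. The groups did not overlap for 299 of the 300, against 9.36% of all tested genes and the 2.86% that chance gives for 4 libraries against 4. The test itself picks genes with such separation, so this is no separate support for the calls. The smallest adjusted p was that of Gadd45a (log2 fold change 2.08 ± 0.16 SE, adjusted p = 0.000146), which lies on chromosome 6 from 67035096 to 67037457 of mm10. Runx1, on chromosome 16 from 92601466 to 92826149, had a log2 fold change of 2.83 ± 0.30 SE (adjusted p = 0.000515). For Chrnb1, on chromosome 11 from 69784036 to 69795943, the value was 1.29 ± 0.12 SE (adjusted p = 0.000394). Ankrd1, on chromosome 19 from 36111965 to 36119844, had 3.30 ± 0.33 SE (adjusted p = 0.000402).

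Other large rises included those of Krt18, a keratin of simple epithelia, Rrad, a small GTPase that inhibits calcium channels, Aldh3a1, an aldehyde dehydrogenase, Plekhh1, Aif1l and Cpne2. Krt18 stood at 0.116 ± 0.0426 CPM in young, 18 reads over the 4 libraries, and at 25.9 ± 19.8 CPM in old vehicle. Chrng, the fetal acetylcholine receptor subunit, likewise rose from 18 reads in young to 756 in old vehicle. Rrad was 22.7-fold, Aldh3a1 16.3-fold, Plekhh1 14-fold, Aif1l 9.34-fold and Cpne2 7.87-fold higher. Falls included those of Kcnf1, a potassium channel subunit, 3.86-fold lower, Irf4 3.41-fold lower, Cacna2d4 3.35-fold lower, Nrep 3.1-fold lower, Sntb1 2.87-fold lower, Adamts3 2.73-fold lower and AI118078 2.66-fold lower.

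**Figure D1:**
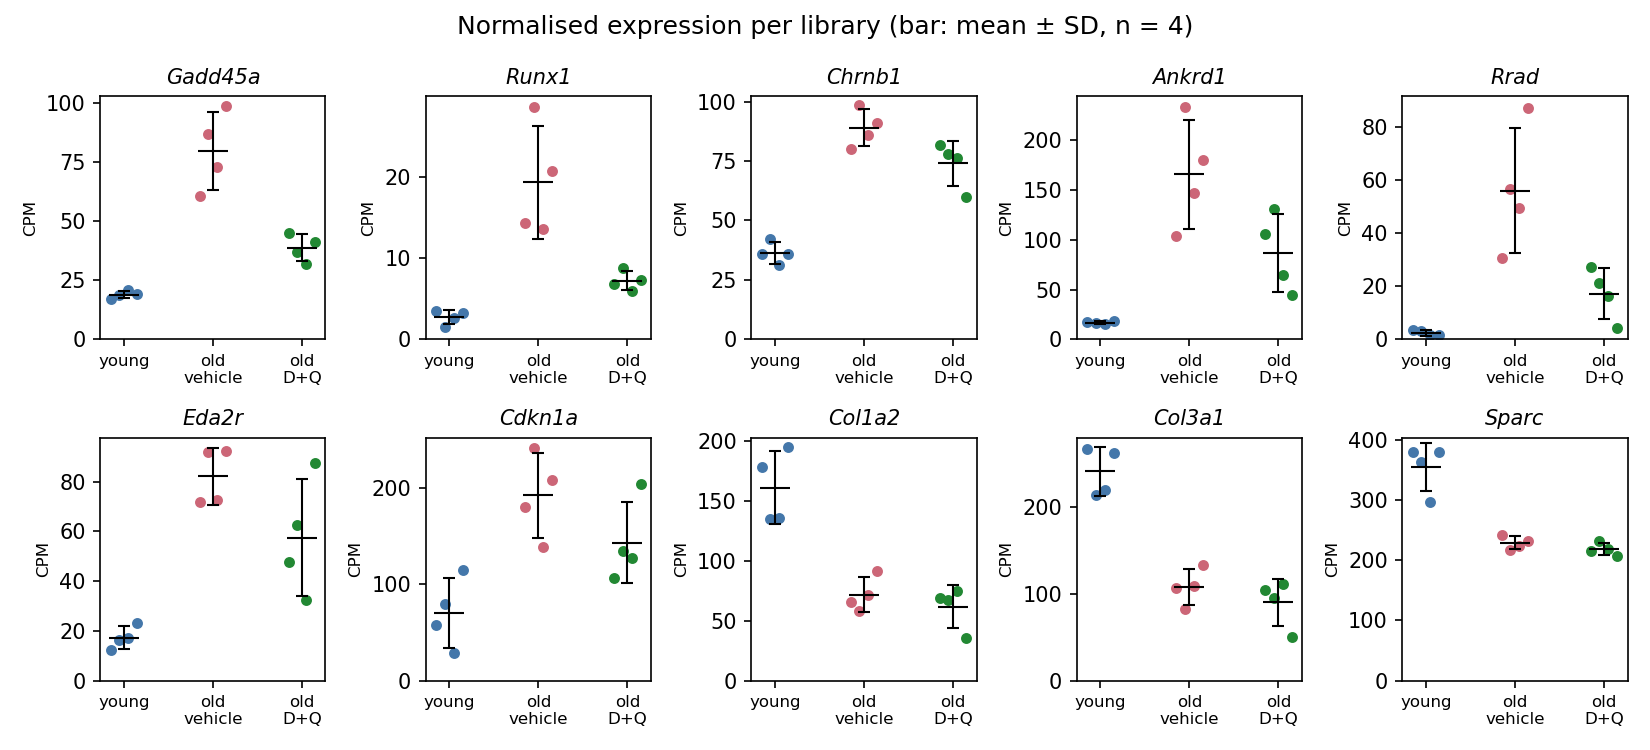
Normalised expression in CPM (vertical axis, from 0) of 10 genes in each of the 12 libraries, by group. Points are libraries and bars the mean ± SD of 4. Gadd45a stands at a mean of 18.9 CPM in young, 79.7 in old vehicle and 38.7 in D+Q.

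Genes linked to senescence gave mixed values. Cdkn1a, the p21 cell cycle inhibitor, was 2.74-fold higher in old vehicle, 192 ± 43.7 CPM against 70 ± 36.2 CPM (SD, n = 4), and missed the threshold (edgeR adjusted p = 0.0545). It passed in 10 of 22 other settings, some of them chosen after seeing the data, with adjusted p from 0.00177 in DESeq2 to 0.146 in edgeR without old vehicle replicate 4. Cdkn2a, which encodes p16, had 1 read in all young, 5 in all old vehicle and 2 in all D+Q libraries, and Gdf15 had 1, 7 and 14. Il6 had 24, 17 and 26 reads. These 3 genes were below the filter and were not tested for a difference. Cdkn2b and Ccl2 had log2 fold changes of -0.32 and 0.22, neither past the threshold. Of 86 tested senescence-associated secreted factors and receptors, 4 rose (Cxcl10, Igfbp2, Egf and Icam1, the last named after its value was seen) and 1, Igf1, fell. Adjusted over the list alone, 4 rose and 2 fell, and the list median was 0.002 (camera adjusted p = 0.78). Cxcl10, an interferon-induced chemokine, went from 28 reads in young to 360 in old vehicle. Among 23 p53 target genes, Eda2r, a receptor of the tumour necrosis factor family, rose 4.76-fold and 22 did not pass (list adjusted p = 0.388), against 4 higher and 2 lower adjusted over the list alone. Among 15 cyclin-dependent kinase inhibitors and arrest regulators, Gadd45a and Rb1 rose, with 3 higher and 1 lower adjusted over the list alone. Gadd45a is also in the denervation list. Of the 15 members 8 were positive and 7 negative, with a median of 0.098 (camera adjusted p = 0.0236, and adjusted p = 0.406 with an estimated correlation). The list's call ended without young replicate 1 or 2 (adjusted p = 0.103 and 0.0568). Its median was 0.009 without young replicate 1 and 0.007 without old vehicle replicate 1. Fry, a rotation test, was also run for changes in either direction. It called the arrest regulators (adjusted p = 4.68e-08), the p53 targets (adjusted p = 4.95e-06) and the secreted factors and receptors (adjusted p = 0.00116). These lists were not tested without their called members.

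The collagen and extracellular matrix list had 34 of 40 members negative and a median of -0.34, with 13 lower when adjusted over the list alone. Postn was 2.32-fold and Sparc 1.55-fold lower, while Col1a1 (1.85-fold lower, adjusted p = 0.228) did not pass. Col1a1 passed in 4 of 22 other settings, all chosen after seeing the data, and its adjusted p over the 22 ran from 0.000444 to 0.377. Tenocyte markers had a median of -0.70, with Col11a1, a fibrillar collagen, called lower, 8 lower adjusted over the list alone, and adjusted p = 0.000515 (adjusted p = 0.406 with an estimated correlation). Fibro-adipogenic progenitor markers were split, with Cd34 and Fbn1 lower and Cxcl14 higher, and 3 lower and 1 higher adjusted over the list alone (list adjusted p = 0.111).

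Macrophage, B cell and antigen presentation lists had positive medians and were called by camera. T and NK cell and neutrophil markers had medians of 0.019 and 0.002 and were not called. Macrophage markers had 21 of 25 positive members and 1 called higher, Cd68, a lysosomal protein of macrophages (list median 0.36, adjusted p = 0.00163, and adjusted p = 0.757 with an estimated correlation). B cell and plasma cell markers had a median of 1.05 with Ighg2c, an immunoglobulin heavy chain, 4.67-fold higher and 3 members higher when adjusted over the list alone (list adjusted p = 0.00196, and adjusted p = 0.406 with an estimated correlation). Immunoglobulin genes share sequence with one another, so the split of reads between them is uncertain. Antigen presentation genes had 20 of 21 positive members and none called (adjusted p = 0.000728, and adjusted p = 0.901 with an estimated correlation). Haemoglobin and red cell genes had a median of 1.47 and none called (adjusted p = 0.0274, and adjusted p = 0.769 with an estimated correlation). The denervation list, with adjusted p = 3.13e-32, kept its call with an estimated correlation (adjusted p = 0.0284) and in the rotation test fry for a change on balance in 1 direction (adjusted p = 0.0019), which called no other list. Fry's test for changes in either direction called 12 of the 29 lists. The macrophage call ended without young replicate 2 (adjusted p = 0.0513) or old vehicle replicate 1 (median 0.22, adjusted p = 0.127). The haemoglobin call ended without young replicate 1 (adjusted p = 0.0919) or old vehicle replicate 3 (median 0.91, adjusted p = 0.0782). The antigen presentation median of 0.34 was 0.60 without young replicate 2 and 0.06 without young replicate 4.

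Lists of fibre type and metabolism were not called. Myh1, the fast 2X myosin, was 1.54-fold higher (adjusted p = 0.0114), while Myh4 and Myh7, the fast 2B and slow myosins, did not pass. The list medians were -0.07 for fast fibre genes (adjusted p = 0.957), -0.35 for slow fibre genes (0.0801), -0.01 for nuclear-encoded oxidative phosphorylation (0.242), with Ndufb2 called lower, 0.09 for glycolysis (0.971), with Pfkfb3 2.26-fold lower, and -0.09 for fatty acid oxidation (0.561). Muscle atrophy and autophagy genes had a median of 0.08 (0.362), satellite cell markers 0.07 (0.734), heat shock genes -0.09 (0.286) with Hspb8 2.18-fold higher, and circadian clock genes -0.15 (0.971) with Per2 2.24-fold and Cry2 1.52-fold higher. Medians were 0.26 for interferon-stimulated genes (0.0574), -0.52 for adipocyte (0.362), 0.09 for endothelial (0.477), 0.09 for pericyte (0.477), -0.26 for Schwann cell (0.0801), 0.02 for T and NK cell (0.971) and 0.00 for neutrophil markers (0.796), 0.04 for immediate early genes (0.641) and 0.14 for proliferation genes (0.557). Values in parentheses are camera adjusted p over 29 lists. The camera direction was opposite to the median for fast fibre, satellite cell, heat shock and T and NK cell genes, and to the mean for immediate early and oxidative phosphorylation genes. Slow fibre genes were negative in 12 of 14 and were called lower without young replicate 3 or old vehicle replicate 3 (adjusted p = 0.00269 and 0.000123). Of the 21 lists not called, 8 were called in at least 1 fit without 1 library, among them interferon-stimulated genes, higher without young replicate 3 (adjusted p = 0.00013), and adipocyte markers, lower without young replicate 4 (adjusted p = 0.000475). Adjusted over the list alone, 8 oxidative phosphorylation genes were lower, 4 heat shock genes higher and 1 lower, 1 satellite cell marker higher and 3 lower, and 2 clock genes higher and 1 lower.

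The count of called genes moved with the libraries and the tool used. Without young replicate 1, 2, 3 or 4 it was 175, 1022, 158 or 184, and without old vehicle replicate 1, 2, 3 or 4 it was 190, 163, 151 or 146. It was 80 without young replicates 3 and 4, a fit chosen after seeing the data, and 778 with DESeq2. Of the 40 named called genes, 18 kept their call in every fit without 1 library and 0 changed sign. Camera called 14 lists in place of 8 without young replicate 4.

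**Figure D2:**
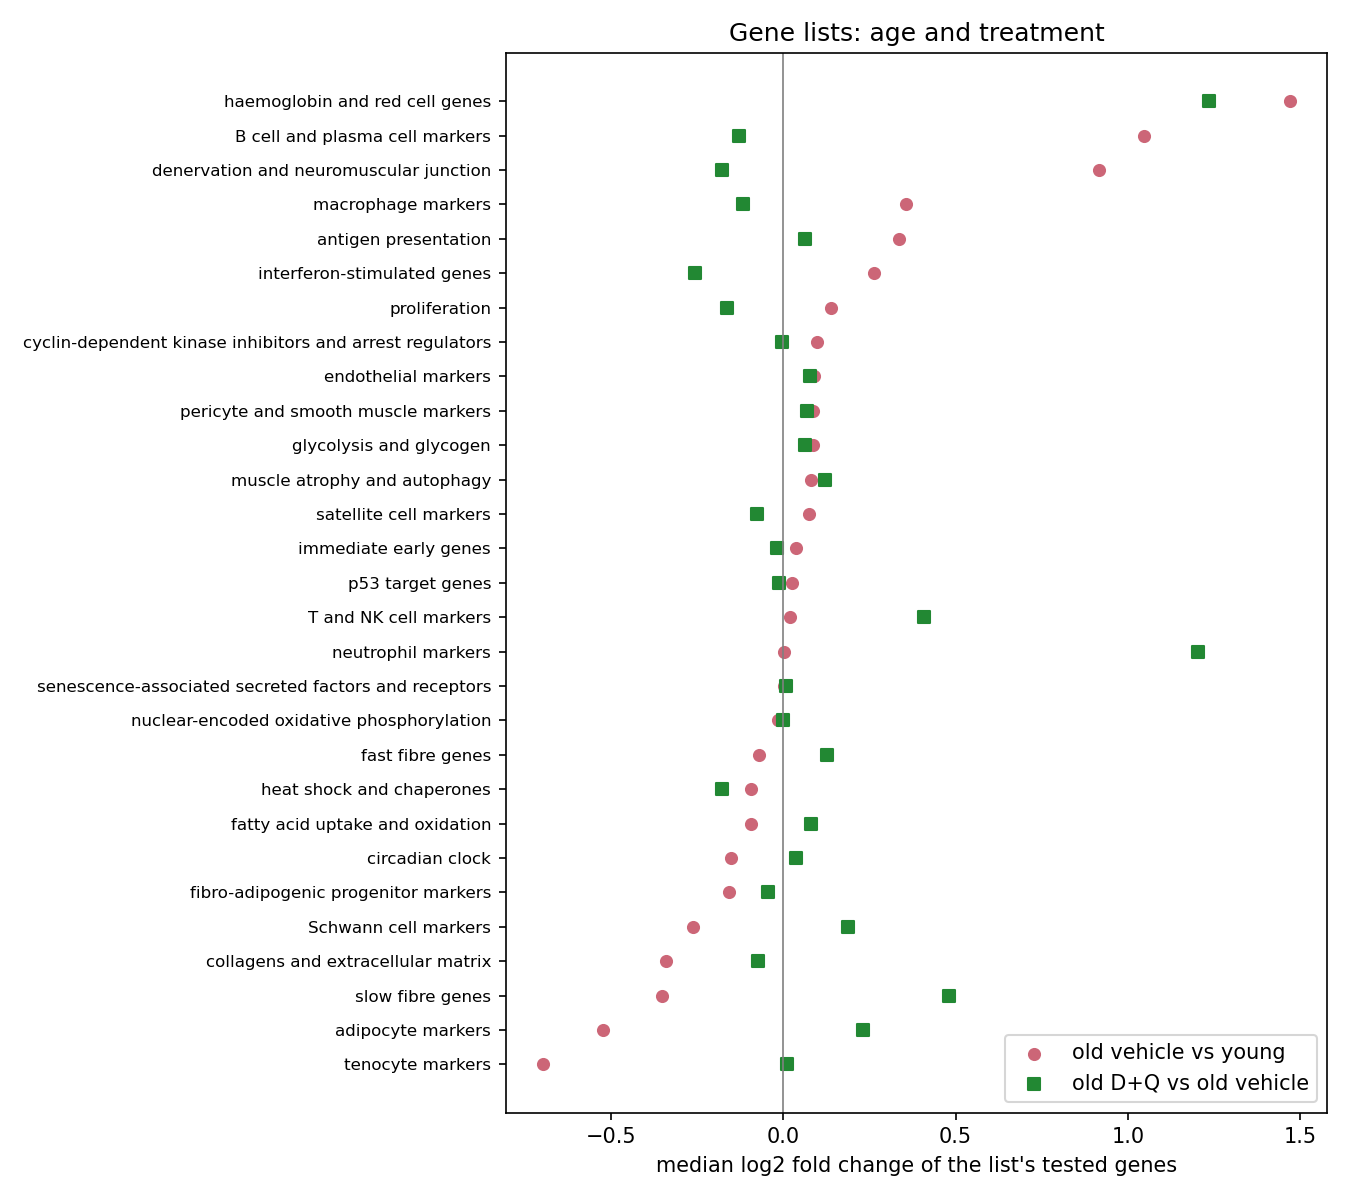
Median log2 fold change (horizontal axis) of the tested genes of each of 29 gene lists (vertical axis), for old vehicle against young (circles) and D+Q against old vehicle (squares). The denervation list has medians of 0.92 and -0.18.

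The second comparison asked what D+Q changed in old muscle. No gene passed, and the values given are those of the genes with the smallest p. Gadd45a stood at 38.7 ± 5.71 CPM in D+Q and 79.7 ± 16.5 CPM in old vehicle (SD, n = 4), 2.06-fold lower. Runx1 was 2.68-fold lower, at 7.19 ± 1.18 CPM against 19.3 ± 6.95 CPM. Nabp1, a single-stranded DNA binding protein, was 1.95-fold lower and Tnfrsf23, a decoy receptor, 1.58-fold lower.

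In the edgeR test, 0 of 16146 genes were called and 349 had an unadjusted p under 0.05, which is 2.16% of the genes. limma-voom also called 0, while DESeq2 called 12, of which 9 were lower and 3 higher, Gadd45a, Runx1, Nabp1 and Tnfrsf23 among the lower. The edgeR log2 fold change of Gadd45a was -1.04 ± 0.15 SE (adjusted p = 0.221), that of Runx1 -1.42 ± 0.28 SE (adjusted p = 0.833), and that of Nabp1, on chromosome 1 from 51465862 to 51478425, -0.96 ± 0.18 SE (adjusted p = 0.804). Mfsd7a was 2-fold, Sh3d19 1.53-fold and Sh2d4a 1.36-fold lower, and Pla2g5 2.07-fold, Gm26885 1.77-fold and Plekhf1 1.52-fold higher, none past the threshold in edgeR and each but Gm26885 called by DESeq2. On simulated counts with these depths and 4 libraries per group, the same test called 48% of genes changed 2-fold and 91% of genes changed 4-fold in this comparison. Each gene was drawn independently of the others, without a trend shared between genes. Simulations drawn in that way with the age differences kept called a mean of 1140 genes between old vehicle and young, where the data gave 300. Those simulations took the fitted group means, with their error, as true differences, which can add calls by itself. The gap thus does not show how much independent drawing matters. The 48% and 91% may be too high for these data, which was not tested.

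Genes of the senescence lists did not pass over all genes tested. Cdkn1a had a log2 fold change of -0.42 ± 0.34 SE, Eda2r -0.52 ± 0.26, Ccl2 -0.51 ± 0.55 and Cdkn2b 0.10 ± 0.24, each with adjusted p = 1 in edgeR. The median of the 86 secreted factors and receptors was 0.01 (camera adjusted p = 0.559), and 0 passed when adjusted over the list alone. Of 15 kinase inhibitors and arrest regulators, Gadd45a and Rb1 were lower when adjusted over the list alone (adjusted p = 0.000206 and 0.0214). Of 23 p53 targets 0 passed in that way. Col1a1, Mstn, Myh4, Myh7 and Pax7 were not called. Chrng had 185 reads in D+Q against 756 in old vehicle and was not called.

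Of the 29 lists, camera with its preset correlation called 11, 7 lower and 4 higher. None was called with an estimated correlation, where the smallest adjusted p was 0.276, and none by fry's test for 1 direction, where it was 0.678. Fry's test for changes in either direction called 2, kinase inhibitors and arrest regulators (adjusted p = 0.000714) and denervation genes (adjusted p = 0.00553). Both lists hold Gadd45a, the gene with the smallest edgeR p in this comparison (unadjusted p = 1.37e-05), and they were not tested without it. The denervation list had 16 of 25 negative members, a median of -0.18 and 8 members lower when adjusted over the list alone (adjusted p = 1.48e-09, and adjusted p = 0.276 with an estimated correlation). Interferon-stimulated genes were negative in 32 of 33 (median -0.26, adjusted p = 1.02e-08, and adjusted p = 0.435 with an estimated correlation). Macrophage markers were negative in 22 of 25 (adjusted p = 0.00013, and 0.435 as the adjusted p with an estimated correlation). Heat shock genes were negative in 19 of 20, proliferation genes in 17 of 22 and extracellular matrix genes in 26 of 40, with adjusted p = 0.000416, 0.000416 and 0.0387, and adjusted p = 0.462, 0.276 and 0.691 with an estimated correlation. For kinase inhibitors and arrest regulators 8 of 15 were negative with a mean of -0.08 (camera direction lower, adjusted p = 0.00814, and adjusted p = 0.276 with an estimated correlation). Haemoglobin genes were positive in 7 of 7, slow fibre genes in 12 of 14, neutrophil markers in 5 of 5 and Schwann cell markers in 10 of 16, with medians of 1.23, 0.48, 1.20 and 0.19. Their adjusted p-values were 1.15e-07, 1.83e-05, 7.61e-05 and 0.0446, and adjusted p = 0.276, 0.435, 0.276 and 0.691 with an estimated correlation. Adjusted over the list alone, 1 macrophage marker was lower and 2 neutrophil markers were higher. The other 18 lists had camera adjusted p from 0.056 to 0.935, and 11 of them were called in at least 1 fit without 1 library.

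Several of these list values depended on 1 library. The neutrophil median fell from 1.20 to 0.15 without D+Q replicate 4, which ended the call (adjusted p = 0.135). Without the same library the denervation median was -0.05 in place of -0.18, and that of extracellular matrix genes was 0.02, with the camera direction turned and no call (adjusted p = 0.741). Denervation genes had -0.10 without old vehicle replicate 3. Without old vehicle replicate 1 the macrophage median went from -0.12 to -0.03 and the call ended (adjusted p = 0.329). The interferon median was -0.11 without that library and -0.16 without D+Q replicate 2. Extracellular matrix genes were also not called without old vehicle replicate 1 or 4 (adjusted p = 0.0739 and 0.756). Kinase inhibitors and arrest regulators were not called without D+Q replicate 2 or 3 (adjusted p = 0.0915 and 0.0937). Slow fibre genes had a median of 0.19 without D+Q replicate 3 and 0.87 without old vehicle replicate 3. The Schwann cell call ended without old vehicle replicate 3 or 4 (adjusted p = 0.0818 and 0.951) and without D+Q replicate 1 or 3 (adjusted p = 0.0849 and 0.305). Its median was 0.04 without old vehicle replicate 4, where the direction turned, 0.07 without D+Q replicate 3 and 0.30 without old vehicle replicate 2.

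Of the 300 genes called between old vehicle and young, 234 (78%) had a D+Q fold change of the opposite sign. The old vehicle libraries enter both comparisons, and 20 simulations with no effect of age or D+Q gave 91.1 ± 1.59% for the top 300 genes. With the age differences kept and D+Q left as old vehicle, 20 simulations gave 70.6 ± 1.47%, at most 74.93%, over a mean of 1140 called genes. When the 4 old vehicle libraries were split 2 and 2 between the comparisons, the share averaged 77.5% over 6 assignments, from 69.4% to 87.2%. Without young replicate 2 it was 62.6%, over the 1022 genes called in that fit. Across all genes, which are not independent replicates, the fold changes had a Pearson r of -0.32 and a covariance of -0.0354, against a simulated r of -0.493 and covariance of -0.0385 without effects. With the age differences kept and D+Q left as old vehicle, the simulated r was -0.256 ± 0.0152 and the covariance -0.0388 ± 0.0027 (SD over 20 simulations). Without D+Q replicate 4 the r was -0.14. The split gave a mean r of -0.066, from -0.231 to 0.22, and a mean covariance of -0.0067.

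The third comparison set D+Q against young muscle, groups that differ in age, gavage and treatment together. Of the 25 denervation genes all were positive and 6 rose, 19 adjusted over the list alone (list adjusted p = 7.67e-19, and adjusted p = 0.158 with an estimated correlation), with Ankrd1 5.14-fold, Gadd45a 2.05-fold, Chrnb1 2.04-fold and Hdac4 1.67-fold higher. Krt18 was higher at 6.41 ± 3.64 CPM against 0.116 ± 0.0426 CPM (SD, n = 4), and Tmem132b, Plekhh1 and Rrad were 6.11-fold, 6.5-fold and 6.98-fold higher. Haemoglobin genes Hba-a2 and Hbb-bt were 8.1-fold and 7.12-fold higher, with reads shared between near-identical copies, and 5 of 7 genes of that list passed when adjusted over the list alone. Without young replicate 2 the log2 fold change of Hba-a2 was 3.66 in place of 3.02. Both lost their call without young replicate 1, 3 or 4 or D+Q replicate 2, 3 or 4, and over 22 settings the adjusted p of Hba-a2 ran from 1.24e-05 to 0.345 and that of Hbb-bt from 9.9e-06 to 0.345. Of the 40 collagen and extracellular matrix genes 7 fell, 15 adjusted over the list alone, among them Col3a1, 2.67-fold lower, Col1a2, 2.61-fold lower, and the non-collagens Postn and Sparc. The list had adjusted p = 1.52e-11, and adjusted p = 0.268 with an estimated correlation. Nrep, Cacna2d4, Wif1, Postn and Adamts3 were 3.96-fold, 3.81-fold, 3.2-fold, 2.54-fold and 2.45-fold lower.

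In edgeR, 144 genes passed, 85 higher and 59 lower, 143 of them with groups that did not overlap, a separation that the test itself picks. Of all tested genes 6.69% did not overlap, and chance gives 2.86%. Eda2r was 3.33-fold higher (adjusted p = 0.0118) and Ighg2c 5.19-fold higher (adjusted p = 0.00372). Chodl, Igf1, Cd34 and Fbn1 were lower, and Cdkn1a (2.04-fold higher, adjusted p = 0.184) did not pass. Camera called 8 of 29 lists, 5 higher (denervation, haemoglobin, antigen presentation, B cell and neutrophil genes) and 3 lower (extracellular matrix, tenocyte and fibro-adipogenic progenitor genes). None was called with an estimated correlation, where the smallest adjusted p was 0.158, and fry's test for 1 direction called the denervation list (adjusted p = 0.0135), while that for either direction called 9 lists. Of the 21 lists not called by camera, 5 were called in at least 1 fit without 1 library. Adjusted over the list alone, 4 neutrophil markers and 1 B cell marker were higher, 7 tenocyte markers were lower and 1 higher, and 4 fibro-adipogenic progenitor markers were lower and 1 higher. The neutrophil call ended without young replicate 1 or 2 (adjusted p = 0.0732 and 0.0783) or D+Q replicate 4 (adjusted p = 0.398), where the median was 0.41 in place of 1.64. The fibro-adipogenic progenitor call ended without young replicate 2 or D+Q replicate 4 (adjusted p = 0.0879 and 0.282). Of the 31 named called genes, 12 kept their call in every fit without 1 library and 0 changed sign. The count of genes was 49, 1935, 44 or 71 without young replicate 1, 2, 3 or 4, and 80, 67, 59 or 145 without D+Q replicate 1, 2, 3 or 4. DESeq2 called 610, the fit of only these groups 25, and the fit without young replicates 3 and 4 called 15. Both comparisons with young called 116 genes, 73 higher and 43 lower in both, against 1.03 and 0.384 for independent lists, and they share the young libraries. In simulations, where the 300 and 144 genes with the smallest p were taken whether called or not, 33.5 were shared in the same direction without effects and 124 with the age differences kept. With the young libraries split 2 and 2, the genes called in both ran from 1, where 85 and 1 were called and 0.00526 are expected of independent lists, to 66, where 96 and 4568 were called and 27.2 are expected.

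Libraries of 1 group also differed in how expression followed gene length. The slope of log2 CPM deviation on log2 gene length ran from -0.0374 to 0.0549 in young, from -0.02 to 0.0173 in old vehicle and from -0.0404 to 0.0293 in D+Q. With this slope as a covariate, a fit chosen after seeing the data, edgeR called 1784 genes between old vehicle and young and 612 between D+Q and young. Between D+Q and old vehicle it called 0, with 1017 genes at an unadjusted p under 0.05.

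**Figure D3:**
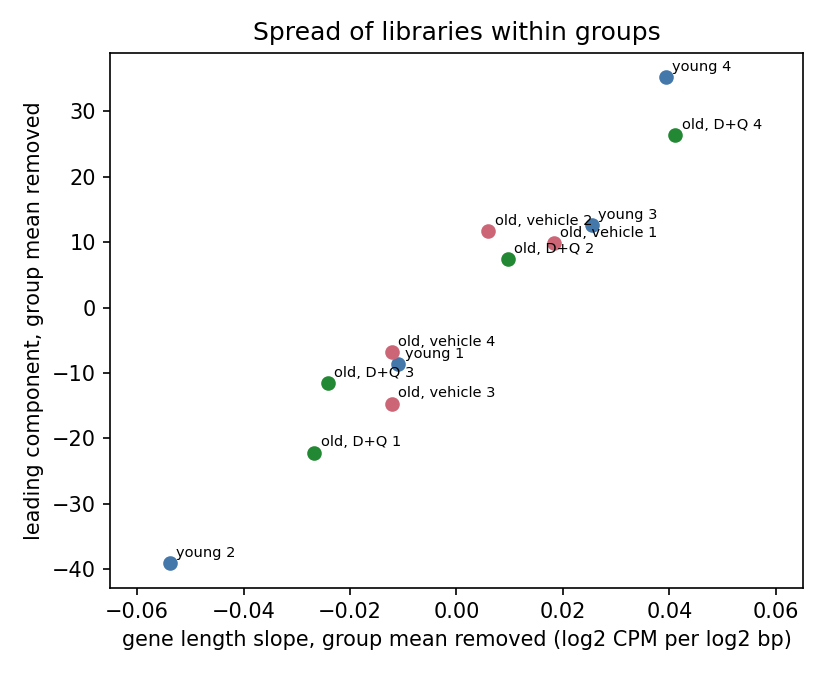
Leading component of expression against the slope of expression on gene length, both with group means removed, for the 12 libraries (points, coloured by group). Young replicates 2 and 4 lie at opposite ends of the component.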

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

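The tests of shared libraries, of the length trend and of the clock genes were chosen after the results were seen. Within each group of 4 libraries, single libraries far from the others were sought in 279 sets of values. 16 were found, 5.73%, and chance gives about 1 in 20.

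Denervation and neuromuscular junction genes had a score of -0.284 in D+Q replicate 4 against 0.353 to 0.426 in the others of that group, and fibro-adipogenic progenitor markers -0.385 in the same library. Mstn stood at 111 CPM there against 52.3 to 58.7 in the others, and Egf at 82.9 CPM. Old vehicle replicate 1 had a macrophage marker score of 0.521, Egf at 81.5 CPM and Myh4 at 26600 CPM. Old vehicle replicate 2 had a fatty acid oxidation score of -0.323, old vehicle replicate 3 had Tmem132b at 5.29 CPM, and old vehicle replicate 4 had Ndufb2 at 87.6 CPM and Sntb1 at 0.884 CPM. D+Q replicate 2 had Col11a1 at 1.32 CPM, Per2 at 9.12 CPM and Plekhf1 at 7.97 CPM, D+Q replicate 3 had Wif1 at 3.74 CPM, and young replicate 2 had Cry2 at 49 CPM.

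Of the genes called between old vehicle and young, 78% had the opposite sign under D+Q. With the length slope as a covariate the share was 83.1%, over the 1784 genes called in that fit in place of the 300. That fit still shares the old vehicle libraries, and simulations with shared libraries and no length trend gave 70.6% and 91.1%. The test thus cannot decide whether a length trend between libraries is a cause. Of the 70 assignments of the 8 old libraries to the 2 groups, 18 gave as large a share, with 94.01% the highest of the others, so chance cannot be excluded. With the old vehicle libraries split, so that none entered both comparisons, the share averaged 77.5%, from 69.4% to 87.2%. For the called genes this argues against shared libraries as the whole cause. The splits reuse the same libraries, however, and no chance spread was computed for their share. Across all genes the split left a mean covariance of -0.0067 in place of -0.0354, so there sharing stays open. An effect of D+Q, by which it would move age-changed genes back, and chance cannot be told apart. Simulations without effects gave 91.1%, for top genes of which none had changed. Simulations with the age differences kept and D+Q unchanged gave 70.6%, at most 74.93%, but called 1140 genes where the data gave 300. Their covariance across genes, -0.0388 ± 0.0027, was no nearer 0 than the observed -0.0354.

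Adding the length slope raised the genes called between old vehicle and young from 300 to 1784. Of the 35 splits only 1, the real one, called as many, with 2 the highest of the others. Those others mix young and old libraries and called at most 1 gene without the slope. They thus cannot show whether the covariate adds calls by itself. Within groups, the slope and the leading component, from separate sets of genes, correlated over 12 libraries at r = 0.975 (exact permutation p = 0.000289, adjusted 0.000434) and rho = 0.937 (exact permutation p = 0.000868, adjusted 0.0013), with r = 0.957 without the 2 libraries farthest from the median slope. Of the other 2 relations tested, a slope on GC content gave r = -0.984 (rho = -0.944, exact permutation p = 0.000289 and 0.000651), so length and GC content were not separated, and total reads gave r = -0.407 (rho = -0.434, exact permutation p = 0.275 and 0.188). A trend of length or GC content between libraries may thus hide age differences. A share of cell types other than muscle stays open, with 4 of 12 marker lists lower along the component and 0 higher. A list was taken as lower where its mean r lay over 2 SE below 0. That SE was taken over the genes of a list, which are not independent replicates, so it is likely too small. Adipocyte markers had the largest mean r with the component of the 12 lists, -0.658 ± 0.0511 SE over 20 genes. The others lower were endothelial (-0.376), Schwann cell (-0.349) and B cell markers (-0.189). The mean log2 CPM of adipocyte markers was 6.31 in young replicate 2 and 2.95 in young replicate 4. Muscle lists were not set against the component. In the same 2 libraries fast fibre genes had means of 12.73 and 12.16 and slow fibre genes 8.06 and 7.53. Glycolysis genes had 9.66 and 9.21, and muscle atrophy and autophagy genes 5.97 and 5.98. The fall between these libraries was thus not limited to genes of cell types other than muscle. No other biological explanation was tested.

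Clock genes set old vehicle replicate 3 apart, with Dbp at 71.7 CPM against 8.94 ± 1.28 CPM in the other 3 libraries and Arntl at 30.4 CPM against 63.1 ± 2.14 CPM, genes chosen after their values were seen. The length slope of that library, -0.0134, lay inside the range of the other libraries, which argues against the length trend. Without Dbp and Arntl, the median of 8 genes in phase with Dbp was 0.355 and that of 4 in phase with Arntl -0.815, a gap of 1.17 log2. This is consistent with another time of collection, a hypothesis for which the labels give no time.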

How the results depend on the processing

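Fits with the length slope, surrogate variables, library weights or without young replicates 3 and 4 were chosen after seeing the data, and the cause of the changes was not tested. Of the values of named genes and lists under the settings fixed beforehand, 1842 kept direction and side of the threshold, 354 fell below it, 21 passed it and 23 turned direction, and under the added settings 548, 60, 20 and 14. For old vehicle against young, 300 genes (195 higher, 105 lower) became 778 (427, 351) with DESeq2, 188 (46 lower) with only the groups compared, 566 (310, 256) at adjusted p under 0.1, 1784 (1077, 707) with the length slope, 1130 (651, 479) with 1 and 1643 (942, 701) with 2 surrogate variables, 678 (338, 340) with library weights and 80 (52, 28) without young replicates 3 and 4. Without 1 library the range was 146 to 1022 (113 to 536, 32 to 486). For D+Q against young, 144 (85, 59) became, in the same order, 610 (322, 288), 25 (22, 3), 357 (184, 173), 612 (368, 244), 581 (333, 248), 740 (436, 304), 1430 (832, 598) and 15 (7, 8), and without 1 library 44 to 1935 (34 to 1067, 10 to 868). For D+Q against old vehicle, DESeq2 called 12 (3, 9) and 2 surrogate variables gave 11, all lower. Without 1 library edgeR called 0 there in each fit, with 233 to 441 genes at an unadjusted p under 0.05.

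Replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.401 to 0.41, 4 of 12 pairs over 0.1, and 3 libraries correlated best with their own number. With the replicate block, 141 (105, 36) genes were called between old vehicle and young, 0 between D+Q and old vehicle, with 267 at an unadjusted p under 0.05, and 35 (26, 9) between D+Q and young.

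For old vehicle against young, D+Q against old vehicle and D+Q against young in turn, 8, 11 and 8 lists became 1, 0 and 0 with an estimated correlation and 1, 0 and 1 with fry for 1 direction (12, 2 and 9 for either direction), and 6 to 14, 10 to 16 and 6 to 12 without 1 library. As many lists were called in 25, 16 and 25 of the 35 splits of the libraries, with 14, 16 and 17 the highest of the others, so chance cannot be excluded for these counts. The 300 genes were reached in 1 of 35 splits, the real one, with 1 gene the highest of the others. This argues against chance but does not exclude it. With 35 splits no permutation p can fall below 0.0286. The other splits also mix young and old libraries, which lowers their counts if age has an effect. For D+Q against young, 3 of 35 splits called 144 or more, so chance cannot be excluded. Young replicates 1, 3 and 4 with D+Q replicate 4 gave 6406 and young replicates 1 and 2 with D+Q replicates 1 and 3 gave 2236, which points to a structure of the libraries. For D+Q against old vehicle, the real split and the others, 35 of 35, called 0 genes, and a count of 0 cannot be tested in this way.

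The opposite-sign share, over the genes called in each fit, was 83.1% with the length slope and 62.6% to 86.3% without 1 library. The correlation was -0.066 with split libraries, -0.439 with the length slope, -0.411 with 1 surrogate variable and -0.421 to -0.144 without 1 library. Log2 fold changes that turned sign without 1 library ranged, for old vehicle against young, from -0.132 to 0.591 for Ccl2 and -0.702 to 0.235 for Myh7. For D+Q against old vehicle they ranged from -0.014 to 0.254 for Cdkn2b, -0.371 to 0.054 for Col1a1 and -0.083 to 0.317 for Pax7, and for D+Q against young from -0.657 to 0.078 for Ccl2, -0.459 to 0.003 for Mstn and -0.183 to 0.081 for Myh4. With library weights Myh4 was 0.024 in D+Q against young, and Cdkn2b was -0.109 and Col1a1 0.081 in D+Q against old vehicle. With the length slope Pax7 was -0.02 in D+Q against old vehicle, and in D+Q against young Ccl2 was 0.027 and Mstn 0.082. In that comparison Ccl2 was 0.242 and Mstn 0.074 with 1 surrogate variable, and Mstn 0.17 with 2 and 0.232 without young replicates 3 and 4.

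For lists the direction of the camera test turned, and the medians given need not change sign with it. Without 1 library, medians of the secreted factor list ranged from -0.019 to 0.051 in old vehicle against young, -0.022 to 0.029 in D+Q against old vehicle and -0.042 to 0.006 in D+Q against young. In D+Q against old vehicle they ranged from -0.108 to 0.024 for extracellular matrix and 0.036 to 0.295 for Schwann cell genes, and in D+Q against young from -0.055 to 0.016 for p53 targets. Without young replicates 3 and 4 the secreted factor list had -0.051 in old vehicle against young and -0.048 in D+Q against young, where it had 0.025 with the length slope and 0.021 with 1 surrogate variable.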
